A study of Mus musculus with 4 samples.

How the data were processed

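Gene expression was measured in immature granulocytes sorted from the bone marrow of male C57BL/6 mice, 2 samples from wild type and 2 from miR-223 KO mice. Per the labels' protocols, total RNA was purified with on-column DNase digestion and its quality was checked, and Cy3-labelled cRNA was made with a low-input kit. Each sample was hybridised alone to a mouse whole-genome array in a single colour. Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1, which detrended each array and subtracted background, so the deposited intensity of a spot is its background-subtracted processed signal, not scaled between arrays; signals at background carry surrogate values. Mean spot and local background intensities are deposited in the same files. The authors' deposited value table holds log2 values. Against the scanner files each of its columns tracked log2 processed signal with an offset per array (Pearson's r across 41174 probes 0.9999 or higher, all column medians 4.68), so its scale and centring were read from the data. The probe annotation of the files is on mm9.

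Log2 processed signals had the 75th percentile over non-control spots of each array subtracted. Spots of a probe were averaged, outlier spots (75 to 81 per array) being kept and left out in an alternative. Probes well above background on at least 2 of the 4 arrays were kept (25749 of 41174), and a gene was represented by its brightest probe, giving 16988 genes. In 5896 genes several probes passed, and in 610 of these the log2 differences of the probes differed in sign and by over 0.5. Gene names were updated through a RefSeq gene table of GRCm38.p6: 26933 probes were named through their accession, 5570 carried a current symbol, 894 were named through a synonym and 7777 kept the name in the files. No coordinates of that table were used.

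Differences between genotypes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, adjusted p under 0.05), without a replicate block. With 2 arrays against 2, no exact test across arrays can pass 0.05, so tests rest on the spread that limma shares across genes (prior degrees of freedom 1.83). Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 32 lists. The alternative was camera with an estimated correlation. That version also refers its statistic to the few residual degrees of freedom of 4 arrays, which makes a pass hard to reach whatever the correlation. The lists, fixed before the data were examined from general knowledge, cover reported miR-223 targets, granule types, cell cycle, ribosome, metabolism, stress, interferon and inflammation, lysosome, signalling, transcription factors, neighbours of Mir223, genes that report sex and markers of other cell types. Within a list, members were counted over all genes and adjusted over the list alone.

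Genes named in the text were chosen by a rule fixed in advance: the 12 with the largest change in each direction among those that pass with both KO arrays on the same side of both WT arrays or, where fewer pass, the 12 with the smallest p in that direction, leaving out clone and accession names; up to 4 members per list with the smallest p; and Mef2c and Igf1r. Genes with a seed match were to be named if they passed, and 0 did.

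The planned test of miR-223 seed matches in 3' UTRs was not run, since UTR sequences were not used here. In its place, chosen after the files were seen, matches were searched in the 60-base probe sequences, which are in the sense of the transcript and can lie in any part of it. Mean log2 differences were compared with those of genes without a match by a two-sided permutation test over genes (100000 resamples; genes are not independent replicates). In the alternatives the background correction, scaling, starting values, filters, probe rule, variance prior, threshold, block and the arrays used were changed in turn. Values given with normexp, unless fitted without control spots, were affected by an extreme control spot on the WT replicate 1 array, described below.

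The procedure was tested on 20 simulated data sets of 16988 genes with the mean signals of these arrays and residual spreads drawn from genes of similar signal. Of genes changed by 2 on the log2 scale 61.3% were called, of those changed by 1 13.1% and of those changed by 0.5 0%, and 0.0116% of unchanged genes were called. With the intensity trend the shares were 69.6%, 32.8%, 6.04% and 0.0176%. Lists of 30 genes shifted by 0.3 were called at an unadjusted p under 0.05 in 20 of 20 data sets by both camera and the permutation test, and unshifted lists in 0. The simulated genes were independent of each other, so this cannot show how often lists of correlated genes are called wrongly. In each data set 16758 genes were unchanged, whereas 23.8% of the measured genes had an unadjusted p under 0.05. The shares of genes called need not hold for these data.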

Results

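RNA from immature granulocytes, the neutrophil precursors of bone marrow, was profiled on 1-colour arrays from male C57BL/6 mice that were wild type (WT, 2 arrays) or lacked the microRNA miR-223 (miR-223 KO, 2 arrays). miR-223 is a small regulatory RNA that is abundant in myeloid cells and lowers the transcripts it pairs with, and the comparison asks which transcripts differ in its absence. All 4 arrays lay on 1 slide and were scanned once, with the genotypes alternating along the slide. Between 59.6% and 62.9% of the spots were well above background, 0 spots were saturated, and the 75th percentile of the processed signal was 314 and 310 in WT and 361 and 422 in KO. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

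No probe on the array is annotated to Mir223 itself (0 of 41174 probes), so the deleted gene could not be used to check the genotype labels. Of the genes next to Mir223 on the X chromosome, 3 were measured. Msn, which encodes the membrane-cytoskeleton linker moesin, had a log2 difference (KO minus WT) of 0.27 ± 0.09 (SE, n = 2 arrays per genotype) and Las1l one of 0.06 ± 0.11. Values of the third, and the count adjusted over the list alone that rests on them, are left out here. Of the 3, 0 passed over all genes, and the list, the third included, did not pass camera (adjusted p = 0.0924). Of 5 genes that report the sex of the cells, 4 were measured, Y-linked Uty among them (log2 difference -0.43 ± 0.09). That list did not pass either (median 0.09, camera adjusted p = 0.92). Its only member past the threshold adjusted over the list alone was Uty (1 lower, adjusted p = 0.0361), and over all genes 0 passed. With an intensity trend in limma the SE of Uty was 0.27 and its adjusted p over all genes 0.349.

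The RNA from the KO sorts held more transcripts of reported miR-223 targets, of interferon-induced genes, of immediate early and heat shock genes, of lysosomal and azurophil granule proteins and of monocyte and eosinophil markers, and fewer of mitotic and erythroid genes, when each list was tested as a group at a preset correlation between genes. With an estimated correlation 0 of the 32 lists passed (smallest adjusted p = 0.445), and single genes did not pass. Correlation alone does not account for that loss in every list. Its estimate was -0.007 for the targets and -0.0036 for G1/S genes, under the preset 0.01. In the other lists that passed at the preset it was higher, from 0.038 for stem and progenitor markers to 0.77 for dendritic cell markers. Mitotic genes had 0.395, immediate early and heat shock genes 0.43 and interferon-induced genes 0.0935. For all of these other lists the p-values at the preset assume less correlation than was estimated. Across 16988 genes limma gave 0 genes at an adjusted p under 0.05, the smallest adjusted p being 0.0839. At an unadjusted p under 0.05 it gave 4044 genes, 23.8% of those tested, of which 2007 were higher and 2037 lower in KO, and 424 genes differed by at least 2-fold (239 higher, 185 lower). The count at an adjusted p under 0.05 depended on the settings. With an intensity trend in its prior variance limma called 1625 genes (925 higher, 700 lower), and without the trend but only on genes well above background on all 4 arrays it called 125. The counts of 0 list members over all genes given below hold without the trend. With it, 31 of 38 mitotic genes were lower and 1 higher, 19 of 34 interferon-induced genes were higher and 0 lower, and 16 of 31 monocyte and macrophage markers were higher and 1 lower. It called 4 after quantile normalization, 61 on the authors' deposited values and 1885 with normexp background correction fitted without control spots, a setting added after seeing the data.

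In 58.5% of genes both KO arrays lay on the same side of both WT arrays, against the 33.3% that chance gives for 2 against 2 arrays. In the other 2 ways of pairing the arrays 20.1% and 21.4% of genes were separated, and 419 and 386 genes had an unadjusted p under 0.05. Each gene is separated in a single pairing, so these lower shares follow from the 58.5% and are no independent comparison. The 419 and 386 are lowered too, since the genotype difference enters the spread within those pairs. With 3 such pairings no share under 0.05 can arise. Across genes, which are not independent replicates, Pearson's r was 0.994 between the WT arrays, 0.994 between the KO arrays and 0.988 to 0.99 between genotypes. The median absolute log2 difference was 0.12 between the WT arrays, 0.14 between the KO arrays and 0.20 between the genotype means.

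The 12 named genes with the smallest p among those higher in KO did not pass the test (adjusted p = 0.0839 for each). They were led by Sdc2, the cell surface proteoglycan syndecan 2, which was 6.71-fold higher (log2 difference 2.75 ± 0.10 SE, n = 2 arrays per genotype; probe at mm9 chromosome 15, 32962294 to 32962353). Fkbp9, a prolyl isomerase of the endoplasmic reticulum, was at 2.25 ± 0.09, and Hspa1a, the inducible HSP70 chaperone, at 1.69 ± 0.08. Rhob, a small GTPase reported as a miR-223 target, was at 1.30 ± 0.08 (mm9 chromosome 12, 8504751 to 8504810). Values for the others were 1.66 for Tmem106b, a lysosomal membrane protein, 1.62 for Ambp, 1.58 for the ascorbate transporter Slc23a2, 1.41 for Klhl5, 1.38 for the palmitoyltransferase Zdhhc2, 1.36 for Rab15 and 1.23 for Tax1bp3. Tshz3 was not well above background in WT and was at least 3.08-fold higher in KO, a bound that sets the dim group at the lowest signal called well above background on each array or at its own signal where that was higher. With normexp background correction 3 of these genes turned: Fkbp9 to -0.16, Ambp to -0.17 and Tshz3 to -0.79. That setting was affected by an extreme control spot on the WT replicate 1 array, and none of the 3 turned with control spots left out of its fit.

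The 12 named genes with the smallest p among those lower in KO did not pass either (adjusted p = 0.0839 for each). Cd209f, a C-type lectin, was not well above background in KO and was at least 6.34-fold lower there. Scn2b, a sodium channel subunit, had a log2 difference of -2.86 ± 0.12 (SE, n = 2 arrays per genotype), Tesc one of -1.61 ± 0.13, and Cd3d, a subunit of the T cell receptor complex, one of -1.43 ± 0.08. Dmc1, a meiotic recombinase, was at -1.64, Sgo2a, which protects centromeric cohesion, at -1.42, and Foxm1, a transcription factor that drives mitotic genes, at -0.95. The remaining values were -1.22 for the BMP receptor Bmpr1a, -1.19 for Sema4f, -1.18 for Nup210l, -1.11 for the fatty acid transporter Slc27a4 and -1.09 for Rbm44. With an intensity trend 23 of the 24 genes named in the 2 directions had an adjusted p under 0.05, the exception being Rbm44 (adjusted p = 0.0566).

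**Figure D1:**
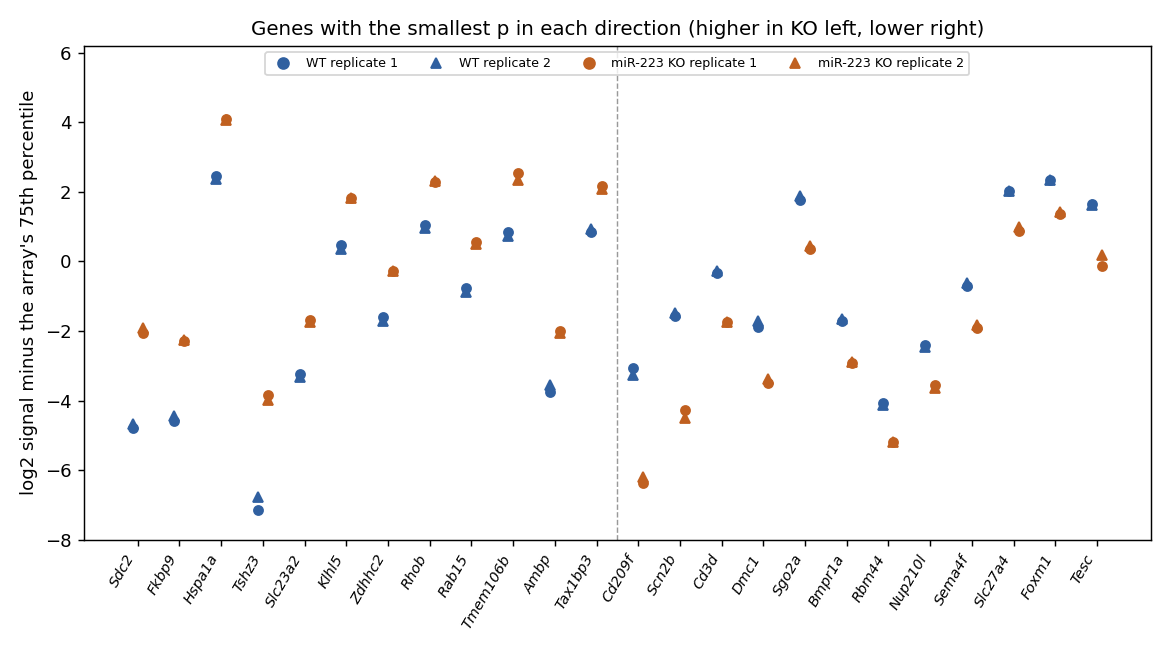
Signal of the 24 genes with the smallest p, 12 in each direction, on the log2 scale relative to the 75th percentile of each array (vertical axis), for each of the 2 WT and 2 KO arrays (points). The replicates of a genotype lie close together and apart from those of the other, for example Hspa1a at a mean of 2.41 in WT and 4.10 in KO. This follows from choosing the genes by their p.

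Reported miR-223 targets rose as a group in KO. Of 29 measured, 25 were higher, with a median log2 difference of 0.28 (SD 0.39 over members; camera adjusted p = 1.15e-06, and adjusted p = 0.445 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 12 were higher, 0 lower and 17 neither. Rhob led the list, followed by the lysosomal protease Ctsz (0.99 ± 0.09 SE), the haematopoietic transcription factor partner Lmo2 (0.80 ± 0.08) and the heterochromatin protein Cbx5 (0.45 ± 0.08). Mef2c, a transcription factor of myeloid progenitors and a target with genetic evidence, had a log2 difference of 0.43 ± 0.09 (adjusted p = 0.119), and the growth factor receptor Igf1r one of 0.43 ± 0.09 (adjusted p = 0.119). Most members also stand in other lists below. Ctsz, Ctsl, Ccl3 and Icam1 are in those of lysosomal, monocyte or inflammatory genes. Mef2c and Lmo2 are in that of myeloid transcription factors, and Igf1r is in that of growth signalling.

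Probes that themselves contain a match to the miR-223 seed gave a second view of the targets, chosen after the files were seen because 3' UTR sequences were not used here. It was not fully separate from the first, since Ccl3 is in both groups. Genes whose 60-base probe holds the 8mer AACTGACA had a mean log2 difference of 0.38 ± 0.14 (SE over 23 genes), 0.395 above genes with no match (two-sided permutation p = 6e-05 over genes; 17 of 23 higher). Those with only a 7mer-m8 match, AACTGAC, lay 0.0216 above (36 genes, permutation p = 0.735), those with only a 7mer-A1 match, ACTGACA, lay 0.0557 above (56 genes, permutation p = 0.286) and those with only the 6mer ACTGAC lay 0.0896 above (128 genes, permutation p = 0.0108). With the 5 tests adjusted together the 8mer (adjusted p = 3e-04), the 6mer (0.0179) and the combined 7mer and 8mer group (0.113 above in 115 genes, permutation p = 0.00235, adjusted p = 0.00587) passed. These 3 groups also passed camera at the preset correlation (p = 0.000112, 0.0126 and 0.00632), and none of them did with an estimated correlation (p = 0.0642, 0.103 and 0.0575). The same motifs read as their reverse complement gave 0.012 (126 genes, permutation p = 0.734). Among the 8mer genes were Parp9 (1.30 ± 0.15), Apool (1.14 ± 0.09), the chemokine Ccl3 (1.03 ± 0.21), the iron-sensing aconitase Aco1 (0.97 ± 0.10) and Dhx33 (0.62 ± 0.11), none of which passed alone and all of which were chosen after their values were seen. The extremes of the group were dim: Fam89a (2.02 ± 0.62) had a WT mean of -6.99 and AK031438 (-1.50 ± 0.47) a KO mean of -6.38. Both means lay below the lowest signals called well above background on the arrays of that genotype. Only on genes well above background on all 4 arrays the 8mer shift was 0.412 (21 genes). Without KO replicate 2 the combined group lay 0.0767 above with a permutation p of 0.0689, and with no filter on dim probes 0.0651 above with a permutation p of 0.0563. The 8mer shift was 0.208 with no filter (38 genes) and 0.257 with the mean over the probes of a gene (34 genes), where any probe can hold the match.

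**Figure D2:**
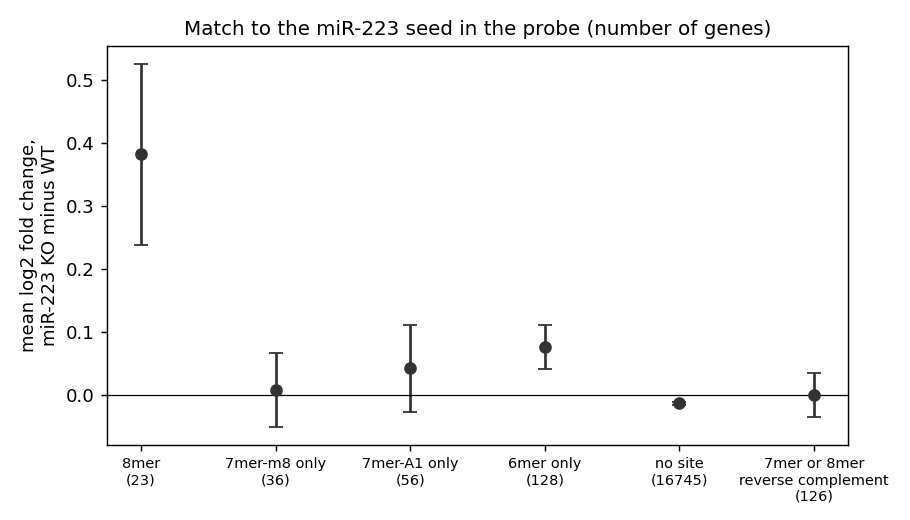
Mean log2 difference between KO and WT (vertical axis) of genes grouped by the strongest match to the miR-223 seed in their probe, with the number of genes in brackets; bars are the standard error over genes. The 8mer group sits at 0.38, above the groups with shorter matches and the genes with no match at -0.01.

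Interferon-induced genes rose together. Of 34 measured, 33 were higher in KO (median log2 difference 0.64, SD 0.39; camera adjusted p = 1.41e-13, and adjusted p = 0.505 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 25 were higher and 0 lower, led by Oas1a (1.20 ± 0.09 SE), a sensor of double-stranded RNA, the exonuclease Isg20 (0.88 ± 0.08), Parp14 (0.81 ± 0.08) and the ubiquitin-like protein Isg15 (1.19 ± 0.13). Genes of NF-kB signalling and inflammation also rose, with 23 of 29 higher and a median of 0.22 (SD 0.39; camera adjusted p = 0.00259, and adjusted p = 0.554 with an estimated correlation), although without KO replicate 1 the median was 0.10 and without KO replicate 2 it was 0.39. Over all genes 0 passed, and adjusted over the list alone 2 were higher: Il1rn, the interleukin-1 receptor antagonist (2.15-fold), and Socs3, a feedback inhibitor of cytokine signalling (log2 difference 1.03 ± 0.13). Ier3 (0.56 ± 0.11) and Ccl3 came next. Monocyte markers, given below, rose alongside these groups.

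Immediate early and heat shock genes, which respond to handling and stress, rose in KO. Of 24 measured, 22 were higher, with a median log2 difference of 0.58 (SD 0.44; camera adjusted p = 1.82e-08, and adjusted p = 0.554 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 14 were higher and 0 lower. Hspa1a stood first, with Hspa1b at 1.54 ± 0.11 SE and the AP-1 transcription factor subunits Jun at 1.23 ± 0.10 and Junb at 0.71 ± 0.09. The unfolded protein and integrated stress response did not pass as a list (median 0.13 in 26 genes, camera adjusted p = 0.0924), though it did without WT replicate 1 (median 0.18, adjusted p = 0.0489), with no filter on dim probes (0.0117), with normexp (median 0.44, adjusted p = 4.7e-06) and with normexp fitted without control spots (0.000716). Its members went both ways: adjusted over the list alone 4 were higher, among them the endoplasmic reticulum proteins Manf (0.56 ± 0.09) and Pdia6 (0.50 ± 0.10), and 4 were lower, among them the ATF4 targets Asns (-0.53 ± 0.08) and Trib3 (-0.54 ± 0.10). Over all genes 0 passed.

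Azurophil granule genes, which belong to the promyelocyte stage, rose in KO: 19 of 20 were higher, with a median log2 difference of 0.29 (SD 0.26; camera adjusted p = 8.29e-06, and adjusted p = 0.554 with an estimated correlation). There were 7 members higher and 0 lower adjusted over the list alone, and 0 over all genes. They were led by the protease-activating cathepsin Ctsc (0.76 ± 0.10 SE), the serine proteases Prtn3 (0.72 ± 0.10) and Ctsg (0.63 ± 0.09) and the growth factor Clec11a (0.77 ± 0.12). The median was 0.63 with normexp. Monocyte markers and stem and progenitor markers, given below, rose alongside. Specific granule genes, which belong to myelocytes, did not pass (median -0.06 in 22 genes, camera adjusted p = 0.656, 0 members past the threshold either over all genes or adjusted over the list alone), and with normexp background correction the list turned to 0.42 (adjusted p = 4.18e-05). Whether the granule lists differ from each other was not tested. The chitinase-like Chil1 had a log2 difference of -0.38 ± 0.10 and the peptidoglycan-binding Pglyrp1 one of -0.31 ± 0.08.

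Genes of gelatinase granules and late neutrophils rose as a list by a narrow margin (26 of 36 higher, median log2 difference 0.22, SD 0.58; camera adjusted p = 0.0337, and adjusted p = 0.65 with an estimated correlation). The list held 6 higher and 2 lower members adjusted over the list alone, with 0 past the threshold over all genes. The stefins Stfa1 (-1.46 ± 0.14 SE) and Cstdc5 (-1.38 ± 0.14), cysteine protease inhibitors, were lower, whereas the C-type lectin Clec4e (0.95 ± 0.12) and the protease inhibitor Slpi (0.75 ± 0.10) were higher. The list did not pass without WT replicate 2 (adjusted p = 0.142) or without KO replicate 2 (adjusted p = 0.318), nor on the authors' deposited values (adjusted p = 0.0585).

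Lysosomal genes rose, with 27 of 31 higher and a median log2 difference of 0.31 (SD 0.33; camera adjusted p = 8.11e-08, and adjusted p = 0.554 with an estimated correlation). Over all genes 0 passed, and 13 were higher and 0 lower adjusted over the list alone. The cathepsins Ctsz, Ctsc and Ctss were at 0.99 ± 0.09 SE, 0.76 ± 0.10 and 0.83 ± 0.11. Monocyte markers moved in the same direction. Genes of the phagocyte oxidase and reactive oxygen handling did not pass (25 genes, median -0.02 and mean 0.02, so that these differ in sign; camera adjusted p = 0.634), though they did with normexp (median 0.41, adjusted p = 2.53e-05) and with normexp fitted without control spots (0.0326), with the antioxidant enzymes Prdx2 at 0.47 ± 0.10 and Cat at 0.39 ± 0.09. Of them 0 passed, over all genes or adjusted over the list alone.

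Cell cycle genes fell in KO, mitotic genes more than replication genes. Of 38 G2/M and mitotic genes 36 were lower, with a median log2 difference of -0.51 (SD 0.25; camera adjusted p = 1.41e-13, and adjusted p = 0.554 with an estimated correlation). While over all genes 0 passed, 32 were lower and 1 higher adjusted over the list alone. The chromosomal passenger subunit Cdca8 (-0.67 ± 0.08 SE), the kinase Plk1 (-0.77 ± 0.10), the spindle motor Kif11 (-0.86 ± 0.11) and the ubiquitin-conjugating enzyme Ube2c (-0.68 ± 0.09) led the list. Of 39 G1/S and replication genes 38 were lower, with a median of -0.22 (SD 0.18; camera adjusted p = 1.15e-06, and adjusted p = 0.445 with an estimated correlation). Of these 1 was lower adjusted over the list alone, the cyclin Ccne1 (-0.68 ± 0.08), and over all genes 0 passed. Next were the cyclin Ccne2 (-0.70 ± 0.11), the chromatin assembly subunit Chaf1a (-0.45 ± 0.08) and the ribonucleotide reductase subunit Rrm1 (-0.38 ± 0.08). Erythroid markers fell alongside. With normexp background correction the mitotic list no longer passed (median -0.15, adjusted p = 0.873) and the G1/S list passed in the other direction (median 0.20, adjusted p = 0.00242), whereas normexp fitted without control spots, a setting added after seeing the data, kept both lists lower.

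Ribosome biogenesis genes rose (31 of 39 higher, median log2 difference 0.12, SD 0.11; camera adjusted p = 0.00577, and adjusted p = 0.65 with an estimated correlation), though not without KO replicate 1 (median 0.06, adjusted p = 0.0696). Polr1b was at 0.26 ± 0.09 SE, Wdr43 at 0.24 ± 0.10, Wdr74 at 0.21 ± 0.08 and Noc2l at 0.20 ± 0.08. Cytosolic ribosomal protein genes rose too (37 of 38 higher, median 0.13, SD 0.09; camera adjusted p = 0.00116, and adjusted p = 0.65 with an estimated correlation), with a median of 0.07 without KO replicate 1 and 0.58 with normexp. Rpl35 was at 0.31 ± 0.10, Rpl28 at 0.24 ± 0.09, Rpl27 at 0.20 ± 0.08 and Rps2 at -0.20 ± 0.09. In neither list did a member pass, over all genes or adjusted over the list alone (0 and 0).

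Lists of energy, sterol, growth and microRNA genes did not pass camera, and 0 of their members passed over all genes. Oxidative phosphorylation had a median log2 difference of 0.05 in 40 genes (adjusted p = 0.155), with cytochrome c, Cycs, at 0.69 ± 0.10 SE, and cholesterol synthesis one of 0.14 in 23 genes (adjusted p = 0.103), with Nsdhl at 0.43 ± 0.09. Cholesterol synthesis passed without WT replicate 1 (median 0.26, adjusted p = 0.00456) and without KO replicate 1 (median 0.20, adjusted p = 0.00573), but its median was -0.00024 without WT replicate 2 (adjusted p = 0.829) and 0.036 without KO replicate 2 (adjusted p = 0.684). All 4 arrays taken, it passed with no filter on dim probes (adjusted p = 0.00926), with normexp (median 0.35, adjusted p = 0.00157) and with normexp fitted without control spots (0.00661), and oxidative phosphorylation passed with the same settings (adjusted p = 0.0235, 2.92e-10 with a median of 0.49, and 0.000263). Glycolysis had a median of 0.03 and a mean of -0.01 in 20 genes (adjusted p = 0.954), with Pfkfb4 at -0.33 ± 0.08, and passed with normexp (median 0.42, adjusted p = 0.000117). In these lists 0 members passed adjusted over the list alone. In IGF, mTOR and growth signalling (median 0.06 in 25 genes, adjusted p = 0.634) 1 gene was lower adjusted over the list alone, the growth factor Igf1 (-1.06 ± 0.09). In the miRNA pathway (median 0.06 and mean -0.01 in 15 genes, adjusted p = 0.997) adjusted over the list alone 1 was higher, the Argonaute protein Ago4 (0.62 ± 0.09), and 1 lower, Tnrc6c (-0.54 ± 0.09). Myeloid transcription factors did not pass (median 0.07 in 43 genes, adjusted p = 0.103, and 0 past the threshold over all genes). Of them 2 were higher adjusted over the list alone, Lmo2 and Egr1 (0.90 ± 0.12), with Klf4 next at 0.87 ± 0.14. The list passed without KO replicate 2 (median 0.13, adjusted p = 0.00975), on the authors' deposited values (0.0492), with no filter on dim probes (0.00926), with normexp (0.00223) and with normexp fitted without control spots (0.0185), whereas the median was 0.018 without KO replicate 1 (adjusted p = 0.461) and 0.042 without WT replicate 2 (adjusted p = 0.156).

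Markers of other cell types differed between the genotypes. Monocyte and macrophage markers rose, with 23 of 31 higher and a median log2 difference of 0.57 (SD 0.59; camera adjusted p = 7.5e-06, and adjusted p = 0.554 with an estimated correlation). The members higher adjusted over the list alone numbered 16 and those lower 3, and over all genes 0 passed. The chemokine receptor Ccr2 was at 0.82 ± 0.08 SE, fibronectin Fn1 at 0.89 ± 0.10, the coagulation factor subunit F13a1 at 0.71 ± 0.08 and the macrophage surface receptor Adgre1 at 0.97 ± 0.12. Without KO replicate 1 the median was 0.37. Eosinophil markers rose as well (10 of 11 higher, median 0.83, SD 0.56; camera adjusted p = 2e-05, and adjusted p = 0.554 with an estimated correlation). Of these 9 were higher and 1 lower adjusted over the list alone, and 0 over all genes, led by the lipoxygenase Alox15 (0.83 ± 0.09), which turned to -0.95 with normexp, Siglecf (0.87 ± 0.10) and the eosinophil ribonucleases Ear3 (0.49 ± 0.08) and Ear6 (1.04 ± 0.20). The median was 0.48 with no filter on dim probes and 0.46 with normexp fitted without control spots. With an intensity trend in limma 8 of the 11 were higher and 0 lower over all genes, and Alox15 did not pass (adjusted p = 0.0884).

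Dendritic cell markers rose (16 of 21 higher, median log2 difference 0.24, SD 0.46; camera adjusted p = 0.00471, and adjusted p = 0.716 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. The leading members were the MHC class II genes H2-Ab1 (0.65 ± 0.13 SE), H2-Aa (0.69 ± 0.15), H2-DMa (0.66 ± 0.15) and H2-Eb1 (0.61 ± 0.15). This list rested on KO replicate 1, without which the median was 0.09, and the median was 0.70 without KO replicate 2. With normexp the median of the list was 0.12 (camera adjusted p = 0.0415). Stem and progenitor markers rose (16 of 19 higher, median 0.36, SD 0.31; camera adjusted p = 0.00353, and adjusted p = 0.554 with an estimated correlation), with a median of 0.14 without KO replicate 1, and with normexp background correction the median was -0.40 and the list did not pass (adjusted p = 0.993). With normexp fitted without control spots the median was 0.059 (adjusted p = 0.0402). Of its members 3 were higher adjusted over the list alone, the adhesion receptor Adgrl4 (0.65 ± 0.08), the transcription factor Hlf (0.61 ± 0.09) and Esam (0.60 ± 0.11), and over all genes 0; Cd34 was at 0.89 ± 0.19.

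Erythroid markers fell, with 17 of 20 lower and a median log2 difference of -0.51 (SD 0.57; camera adjusted p = 0.00399, and adjusted p = 0.554 with an estimated correlation). The list held 9 lower and 1 higher member adjusted over the list alone, and 0 over all genes. It did not pass with normexp background correction (median -0.68, adjusted p = 0.0876), and its median was -0.32 with no filter on dim probes. Hemgn was at -0.79 ± 0.09 SE, the anion exchanger Slc4a1 at -0.62 ± 0.11 and the transcription factor Tal1 at 0.55 ± 0.10. Ank1 was not well above background in KO and at least 1.95-fold lower there, but another probe of Ank1, which the filter on dim probes leaves out, was at 0.10.

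The remaining markers of other cells did not pass camera, with 0 members past the threshold over all genes. T and NK cell markers had a median log2 difference of -0.27 in 20 genes (adjusted p = 0.154), and 1 was lower adjusted over the list alone, Cd3d. The list turned to 0.23 without KO replicate 2 and passed without KO replicate 1 (median -0.54, adjusted p = 0.000102), on the authors' deposited values (0.0393), with normexp (median -1.09, adjusted p = 0.00024) and with normexp fitted without control spots (0.00712). B cell markers had a median of -0.18 in 19 genes (adjusted p = 0.498), with Igll1 at -0.66 ± 0.17 SE, Ighm at 0.54 ± 0.14 and 0 passing adjusted over the list alone. It too turned to 0.23 without KO replicate 2 and passed without KO replicate 1 (median -0.46, adjusted p = 0.00332). Megakaryocyte and platelet markers had a median of 0.32 in 10 genes (adjusted p = 0.154), 0.67 without KO replicate 1 (adjusted p = 0.0272) and 0.56 with no filter on dim probes (adjusted p = 0.004). It was 0.81 without WT replicate 2 (adjusted p = 0.0988), 0.19 without WT replicate 1 (adjusted p = 0.489) and 0.03 without KO replicate 2 (adjusted p = 0.587). Of them 2 were higher adjusted over the list alone, Gp9 (1.19 ± 0.11) and Itgb3 (0.83 ± 0.11), and 1 lower. Basophil and mast cell markers had a median of 0.09 in 13 genes (adjusted p = 0.367), 1 being higher adjusted over the list alone, the interleukin-33 receptor Il1rl1 (1.14 ± 0.12). Stromal and endothelial markers had a median of 0.11 and a mean of -0.12 in 14 genes (adjusted p = 0.82), and passed as lower with normexp (median -1.05, adjusted p = 0.0215). In this list adjusted over the list alone 1 was higher, Tie1 (1.31 ± 0.14), and 2 lower, among them the chemokine Cxcl12 (-1.57 ± 0.15).

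**Figure D3:**
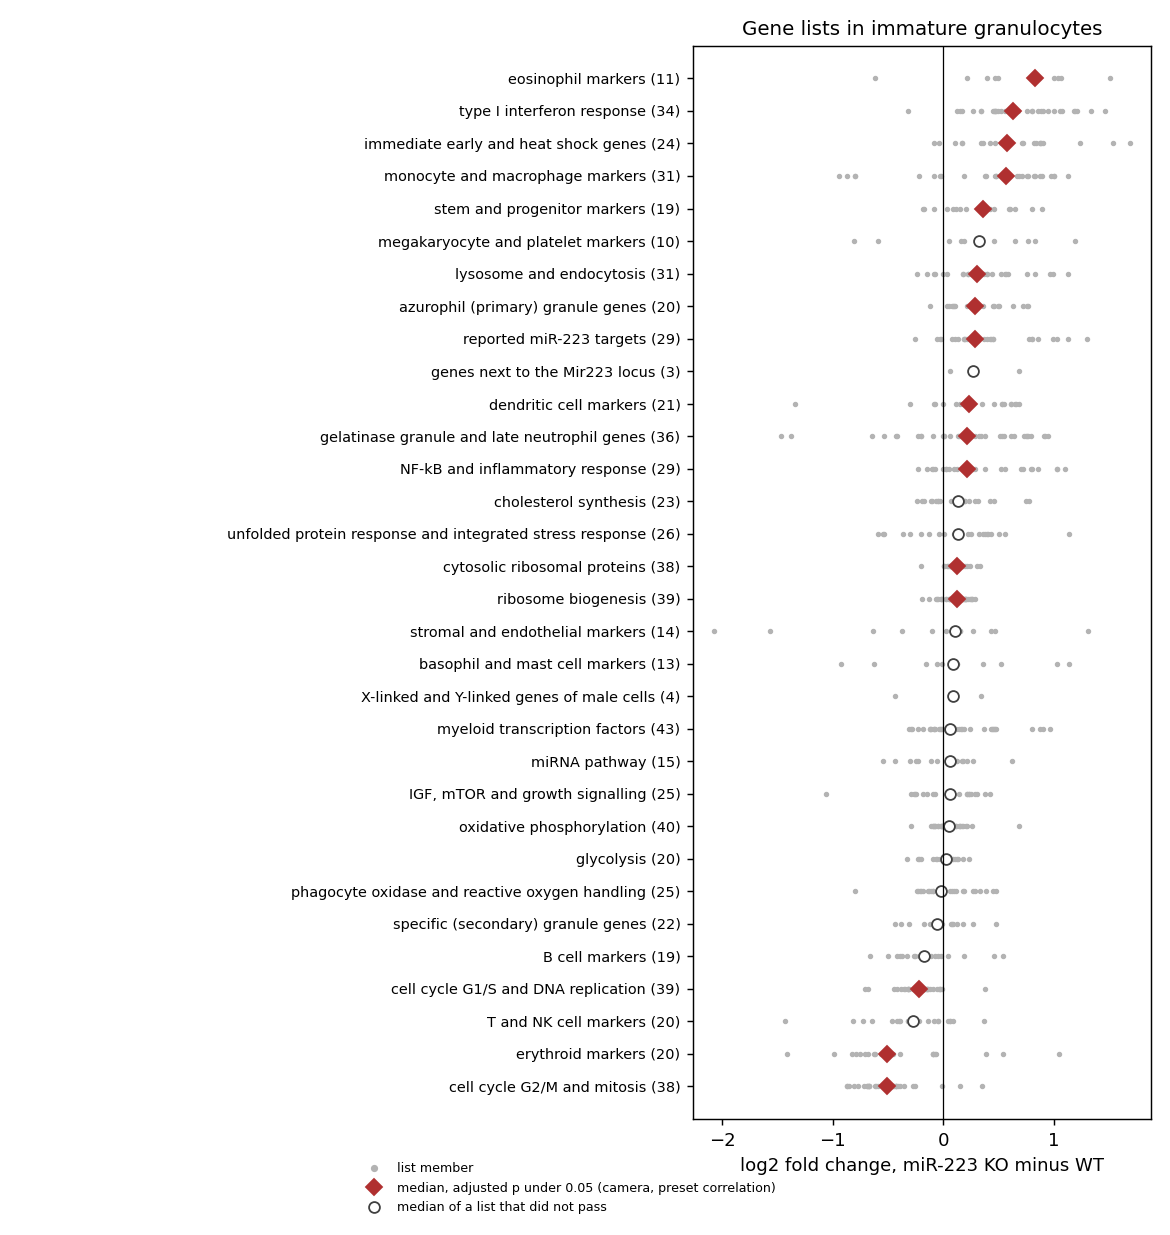
Log2 difference between KO and WT (horizontal axis) of the measured members of 32 gene lists (grey points, number of genes in brackets) and the median of each list. Filled diamonds are the 16 lists with a camera adjusted p under 0.05 at the preset correlation, 13 higher and 3 lower in KO; with an estimated correlation 0 of the 32 passed.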

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

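The seed match results and normexp fitted on the spots that are not controls were chosen after seeing the data; the other alternatives were planned. Settings that need 3' UTRs (their length and GC content, matching by signal among genes with a searched UTR, the shortest UTR) were not run. Signal over background limits dim genes, since 59.6% to 62.9% of spots were well above background.

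The count of 0 genes moved to 4 with quantile normalization (3 higher, 1 lower), 61 on the authors' values (50 higher, 11 lower), 125 on genes well above background on all 4 arrays (87 higher, 38 lower; 15630 genes tested), 1625 with an intensity trend (925 higher, 700 lower), 822 at an adjusted p under 0.1 (463 higher, 359 lower) and 1885 with normexp fitted on the spots that are not controls (901 higher, 984 lower); the cause was not tested. It was 0 with the other settings. Fits without an array leave a genotype with a single array, which is assumed to vary like the pair of the other, so their count of 0 says nothing about stability. The replicate numbers share only a number (deviations correlate at 0.0382 across genes): the fit with a replicate block gave 0 genes and 18 lists, T and NK cell (adjusted p = 0.0355) and megakaryocyte markers (0.0404) being added.

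Lists past the threshold numbered 16, and 15 to 22 in all settings but camera with an estimated correlation, which gave 0 of 32 (smallest adjusted p 0.445). Leaving out an array gave 15 to 18. The 8mer shift stayed above 0 with a permutation p under 0.05 in all settings run (0.317 to 0.474 without an array), but was 0.208 with no filter on dim probes and 0.257 with the mean over probes, against 0.395, and its camera p with an estimated correlation was 0.0642; the cause was not tested. The combined 7mer and 8mer shift lay between 0.0767 (without KO replicate 2) and 0.149 without an array, and was 0.0651 with no filter on dim probes (permutation p = 0.0563). With the mean over probes it was 0.066 in 187 genes (permutation p = 0.021), and with normexp 0.209 (permutation p = 5e-04).

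With planned normexp the lowest log2 value on the WT replicate 1 array rose to -0.64, against -2.75 to -3.06 on the others: the mean signal of a dark-corner control spot there minus its local background was -29869, while the lowest such difference on the others was -2.19, and leaving control spots out of the fit changed the values as given here. The median of all genes moved to -0.15 from -0.02. Across genes the log2 differences correlated at 0.336 with the main ones, and at 0.784 when control spots were left out of the fit. Medians of lists that stayed higher rose to 1.07 for immediate early and heat shock, 0.71 for lysosomal, 0.63 for azurophil granule, 0.48 for late neutrophil, 0.43 for NF-kB and 0.23 for ribosome biogenesis genes. The medians changed sign without a turn of the test for stem and progenitor markers (-0.40), phagocyte oxidase (0.41) and sex-linked genes (-0.081). Lists whose test turned, with their medians, and genes whose value turned under it were 0.42 for specific granule genes, 0.20 for G1/S, -0.50 for basophil, -0.46 for megakaryocyte and -1.05 for stromal markers, -0.16 for Fkbp9, -0.79 for Tshz3, -0.17 for Ambp, -0.15 for Clec11a, 0.046 for Chil1, 0.13 for Pglyrp1, 0.040 for Chaf1a, 0.089 for Rrm1, 0.28 for Rps2, 0.13 for Pfkfb4, -0.95 for Alox15, -0.093 for Il1rl1, -0.40 for Adgrl4, -0.77 for Esam and -0.11 for Tie1. Fitted on the spots that are not controls, 3 results turned: Alox15 (-0.016), and the tests of stromal markers (median -0.14) and specific granule genes (median -0.020).

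The direction of the test also turned, among lists that did not pass, for glycolysis (median 0.019) and the miRNA pathway (0.062) with quantile normalization, stromal markers on the authors' values (0.15), specific granule genes with no filter (-0.059), and growth signalling (-0.067) and the miRNA pathway (-0.058) with the mean over probes. Without an array in turn it changed for glycolysis (medians -0.032 to 0.064), the miRNA pathway (0.0049 to 0.090), B cell (-0.46 to 0.23) and T and NK cell markers (-0.54 to 0.23) and sex-linked genes (-0.074 to 0.25). Las1l turned to -0.0025 without WT replicate 2 and -0.026 without KO replicate 1, and the cause was not tested. Ank1 turned to 0.10 with no filter, where another probe represents the gene.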

Other observations

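The sub-lists and the tests of explanations in this part were chosen after the values were seen, except quantile normalization, which was a planned setting. The 15 genes of the monocyte and macrophage list known from circulating and marrow monocytes had a median log2 difference of 0.71 and the 11 known from resident and erythroblastic island macrophages one of -0.03 (4 higher, 7 lower). The 7 MHC class II genes of the dendritic cell list had a median of 0.61 and the other 14 markers one of 0.16 (9 higher, 5 lower). Of 17 immediate early genes 16 were higher (median 0.71), and of 7 heat shock genes 6 (median 0.58). These divisions followed the values, so they carry no test, and no difference between the sub-lists was tested.

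To see what remains of overlapping lists, lysosomal genes that the monocyte list does not hold were counted, with 24 of 28 higher (median 0.28), and reported miR-223 targets that no other list holds, with 8 of 10 higher (median 0.22). Their camera p-values at the preset correlation, adjusted over the sub-lists of this part alone, were 5.07e-07 and 0.00183. With an estimated correlation their unadjusted camera p-values were 0.0739 and 0.0769. These sub-lists too were chosen after the values were seen, so the p-values only describe them and decide nothing.

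The probe of Cdk12 had the widest gap between replicates of all genes tested. Its log2 signal was 8.31 in WT replicate 2 and -1.48 in WT replicate 1, against -1.83 and -1.75 in KO.

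The first pattern weighed is the higher level of genes whose probe matches the miR-223 seed. Probe GC content and signal level as the whole cause are argued against by the mean difference of 0.103 that remained after regression on both (permutation p = 0.00541). An offset between arrays cancels in a difference between groups of genes and so could not give it. With quantile normalization 0.106 remained (permutation p = 0.00437). Its log2 differences correlated at 0.995 with the main ones across genes, so this was hardly a separate test of scaling. Among 326 7mers of the same base composition the 7mer-m8 motif ranked 2 and the 7mer-A1 motif 5 by mean log2 difference (0.15 in 59 genes and 0.14 in 79), but both groups hold the 23 8mer genes, without which the means were 0.0082 in 36 genes and 0.04 in 56, and the 6mer ranked 84 of 4052 6mers. Loss of repression by miR-223 may account for the pattern and stays open: genes with a 7mer-m8 match but no 8mer lay only 0.0216 above the others (permutation p = 0.735), in 36 genes whose match can lie outside the 3' UTR.

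The second pattern is the rise of monocyte and eosinophil markers beside lower erythroid markers. A lower share of granulocytes in the KO sorts, made up by all other cell types alike, would raise all their markers. Of 20 erythroid markers 17 were lower, which argues against that form of it as the whole cause. The medians of the monocyte and erythroid lists lay 1.075 apart (1.08 rounded, two-sided permutation p = 0.00035 over genes). These lists were picked because they had moved apart, so that test decides nothing. A lower share made up mainly by some cell types, or different shares of several other cell types in the sorts, could give the pattern. The most abundant monocyte list genes, Ly6c1 (0.39), Mpeg1 (0.61), F13a1 (0.71), Ctss (0.83) and Irf8 (0.47), were all higher, whereas the SD over the whole list was 0.59 against a median standard error of 0.17. This cannot be told apart from a change within the granulocytes of KO mice, because no value here separates cell shares from expression per cell and the sort gates are not given in the sources used here.

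The third pattern is the lower level of mitotic genes. With quantile normalization the median was -0.52 (camera adjusted p = 1.37e-14). Camera compares the list with the other genes, so an offset between arrays cancels. The quantile-normalized log2 differences correlated at 0.995 with the main ones, so this was hardly a separate test of scaling. Fewer dividing erythroid cells in the KO sorts are a candidate explanation. The medians of the mitotic and erythroid lists differed by -0.0037 (permutation p = 0.947). Both lists were picked because they had fallen, and a large p does not show that medians are equal, so that test decides nothing. The G1/S list, which the same cells would lower, lay 0.29 above the mitotic list (permutation p = 1e-05, the smallest that the resamples can give). That pair too was compared after its values were seen. The explanation cannot be told apart from a change in the cycle of granulocyte precursors, which was not tested.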
